A study of Homo sapiens with 6 samples.

How the data were processed

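Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in 293T cells, a human embryonic kidney line that carries the SV40 large T antigen. A control line that stably expresses a control short hairpin RNA (shCTL) was compared with a line that stably expresses a hairpin against KDM2B (shKDM2B). Each line gave an H3K79me2 library, an H3K79me3 library and an input library made without antibody, so the 6 libraries form 6 groups of 1 library. Per the labels, the antibodies were Abcam products with the same lot in both lines, and libraries were built with a NEBNext kit. Reads were aligned with Bowtie2 to hg19 (GRCh37), per the submitters' processing notes; its version is not given in the sources used here. Per the file headers, peaks were called separately in each library with MACS 1.4.2. The settings in the headers were no control file, a p cutoff of 1e-05, an effective genome size of 2.7 Gb, a band width of 300 bp, at most 1 tag per position, and a regional background taken over 10000 bp. Because no control file was used, the background of each ChIP peak came from the same ChIP library and not from the input.

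The deposited peak lists give, for each peak, a count of tags, which is a whole number that is not normalized. The deposited fold enrichment is a ratio that the caller computed within the library. The deposited significance column is treated here as a score: its heading names a negative log10 p, but its lowest value is 50 at a p cutoff of 1e-05, so that it is 10 times that quantity. The positions are 1-based. The values per peak are the authors' own and were used to describe, rank or filter peaks within a list.

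The headers also give the depth of each library and the fragment length that the caller estimated. After removal of duplicates the control libraries held 12538191 tags for input, 16018517 for H3K79me2 and 17044011 for H3K79me3. The knockdown libraries held 11912494, 13144744 and 16389356 tags in that order. The estimated fragment length was 148 bp for control H3K79me2, 210 bp for knockdown H3K79me2, 180 bp for control H3K79me3 and 126 bp for knockdown H3K79me3, and 67 and 71 bp for the control and knockdown inputs. The tag size was 47 bp for control H3K79me2, 46 bp for control H3K79me3 and 50 bp in the other libraries. The window that MACS scans grows with the estimated fragment, so peak widths are not comparable between libraries without this in mind.

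Peaks on chromosomes 1 to 22, X and Y were analysed. Overlaps were computed with bedtools 2.31.1 and counted from 1 shared bp; other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Shares carry exact Clopper-Pearson binomial 95% intervals and tags per 1000000 filtered tags (RPM) exact Poisson 95% intervals. Both cover counting error only. With 1 library per group there is no test between the cell lines, no replicate check of any difference and no p-value. For tag comparisons, overlapping peaks of both lines were merged into regions, the tags of each library were summed over its peaks in the region and divided by its filtered tags, and only regions with a peak in both lines gave a ratio. A peak list holds only values above its threshold, so a missing peak is not a value of 0 and gave no ratio and no upper limit. Overlap of the marks was set against 100 placements of the peaks at random on the same chromosome, within the span the lists cover. Joint changes of both marks were set against 10000 draws matched on decile of region length; the draws for lists of equal number were added after the data were seen. The overlap step was tested on simulated data: of 200 private peaks planted among 6827 for H3K79me2 it found 200, with 1 false one, and of 200 planted among 5597 for H3K79me3 it found 200, with 0 false ones. The simulated sites lay far apart. The test therefore checked the overlap code only, and not errors from crowded, split or missed calls.

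The files name no genes, and an annotation of hg19 was not used here, so no peak was assigned to a gene. The comparisons by gene and by fixed gene list that had been planned were therefore not made. The joint change of both marks was counted over merged regions in place of genes. The rule for naming peaks had been fixed for this case as well: the 5 longest peaks of each mark found in 1 line only and outside input peaks. The 3 shared single-peak regions with the largest change of tags per kb in each direction, and the 5 highest-scoring regions with H3K79me2 in both lines and H3K79me3 in 1 line, were chosen after the values were seen, as were the contrast of those last regions with their mirror image and the division of peaks by width with a limit at 7 kb. Before the data were examined, the settings chosen for comparison were the higher-scoring 50% of each list, a minimum fold of 5.67 (the median of the 4 ChIP lists together), the same number of peaks from each list, removal of peaks on input peaks, joining of peaks within 1 kb, a reciprocal overlap of 50%, and counting peaks within 1 kb as shared. Settings added after the data were seen were scores scaled to equal depth, summits within 1 kb, peaks within 10 kb counted as shared, all sequences in the files, removal of peaks over 7 kb, and other scalings of the tag ratio.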

Results

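H3K79me2 and H3K79me3, the di- and trimethylated forms of lysine 79 of histone H3, were mapped in control and KDM2B-knockdown 293T cells. H3K79 methylation is laid down by DOT1L and lies mainly over transcribed genes. KDM2B is a JmjC-domain protein of the histone demethylase family, and the study asked whether it removes methyl groups from H3K79. Each line contributed 1 H3K79me2, 1 H3K79me3 and 1 input library, with 11912494 to 17044011 tags each after duplicate removal. The KDM2B level itself was not analysed here, so the knockdown rests on the labels. With 1 library per group, the differences below are differences between libraries and have no replicate check.

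H3K79me3 occupied more of the genome in the knockdown library than in the control library, whereas H3K79me2 did not. The number of H3K79me3 peaks was 5597 in control cells and 7066 in knockdown cells, a ratio of 1.26. The H3K79me3 peaks covered 17.4 Mb in control cells and 20.4 Mb in knockdown cells. The number of H3K79me2 peaks was 6827 in control cells and 6193 in knockdown cells, a ratio of 0.907, and the covered length was nearly equal, at 20961166 bp and 20957950 bp. The H3K79me3 peaks held 9.76% of the filtered tags in control cells (95% interval 9.75 to 9.78%) and 14.3% in knockdown cells (95% interval 14.29 to 14.33%). The H3K79me2 peaks held 13.05% of the tags in control cells and 10.8% in knockdown cells. These sums move with the length that was called. In tags per 1000000 filtered tags (RPM) per kb of peak, H3K79me3 stood at 5.62 in control and 6.999 in knockdown cells, and H3K79me2 at 6.23 and 5.14. The knockdown H3K79me2 library was the shallowest of the ChIP libraries, with 0.821 of the filtered tags of its control, whereas the H3K79me3 libraries differed less, with a ratio of 0.962.

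**Figure D1:**
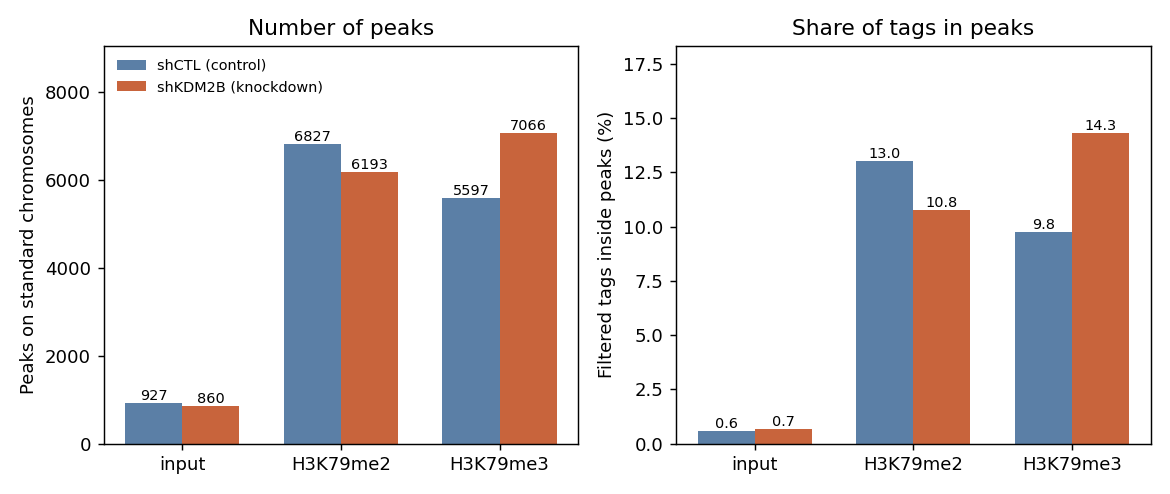
Number of peaks on chromosomes 1 to 22, X and Y (left) and percent of filtered tags inside peaks (right) in each of the 6 libraries; each bar is 1 library, blue for control and orange for knockdown cells. H3K79me3 has 7066 peaks in knockdown against 5597 in control cells, and H3K79me2 has 6193 against 6827.

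Most H3K79me3 sites of control cells were found again in knockdown cells, and the knockdown list added many more. Of the 7066 knockdown peaks, 1921 (27.2%, 95% interval 26.2 to 28.2%) had no overlapping control peak. In the opposite direction 487 of 5597 control peaks (8.70%, 95% interval 7.98 to 9.47%) had no knockdown peak, so that peaks in knockdown only outnumbered those in control only 3.94 times. The peaks in knockdown only were short and weak, with a median width of 1148 bp and a median of 50 tags, against 2821 bp and 265 tags for knockdown peaks with a control counterpart. Those in control only were longer, with medians of 2462 bp and 108 tags. By length and tags the imbalance was therefore smaller than by number. Peaks in knockdown only covered 3.47 Mb and held 11.3% of the tags in their list's peaks. Peaks in control only covered 1.60 Mb and held 8.60%. In the lowest quartile of knockdown H3K79me3 peaks by score, 69.3% lacked a counterpart, and in the highest quartile 0.736% did. When the same number of peaks was taken from each list, 860 peaks were in knockdown only and 862 in control only; lists of equal length force these counts close together.

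For H3K79me2 the balance lay the other way. Of the 6827 control peaks, 1297 (19.0%, 95% interval 18.1 to 19.9%) had no knockdown peak, and of the 6193 knockdown peaks 753 (12.2%, 95% interval 11.4 to 12.999%) had no control peak, a ratio of 0.581. H3K79me2 peaks in control only had a median score of 78.1, against 219 for control peaks with a counterpart. Their median width was 2223 bp, against 2622.5 bp, and they held 18.2% of the tags in the control list's peaks. H3K79me2 peaks in knockdown only held 5.71% of the tags in the knockdown list's peaks. When the caller's scores, but not the reads, were scaled to the depth of the shallower library, 933 H3K79me2 peaks were in knockdown only and 937 in control only. That scaling left 6245 control peaks beside the 6193 knockdown peaks, and lists of nearly equal length force these counts together. The same scaling left H3K79me3 at 1979 and 454.

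In regions that carried a peak in both lines, H3K79me3 was higher in knockdown cells by tags and by tags per kb, whereas H3K79me2 tags were similar and H3K79me2 tags per kb lower. Tags were summed over peaks called separately in each library, so they follow the called width, and the values per kb are given beside them. Over 5087 such H3K79me3 regions the median log2 ratio of tags in RPM, knockdown over control, was 0.60, a 1.52-fold difference, with quartiles at 0.34 and 0.95. It was above 0 in 92.9% of these regions. The difference exceeded the counting error in the upward direction in 4111 regions and in the downward direction in 139. Over 5432 H3K79me2 regions the median log2 ratio was 0.00 with quartiles at -0.25 and 0.37, and by tags 1341 regions were higher and 1300 lower beyond counting error. Knockdown H3K79me2 peaks were wider in 72.7% of the regions, by a median of 0.16 on the log2 scale. Per kb, H3K79me2 was higher in knockdown cells in 28.6% of the regions, with a median log2 ratio of -0.15. For H3K79me3 the median per kb was 0.55, and 96.9% of the regions were higher. The authors' fold enrichment, which the caller set against each library's own local background, differed far less for H3K79me3: its median log2 ratio was 0.09, and 64.6% of the regions were higher. For H3K79me2 it was -0.15, with 26.4% higher. These folds describe peaks within a list and were not used to compare levels. The tag density of a region in control cells tracked that in knockdown cells, with Spearman's rho across regions of 0.933 for H3K79me2 and 0.922 for H3K79me3; regions are not independent replicates. H3K79me3 regions on input peaks differed from the rest, with a median log2 ratio of -0.37 in 209 regions against 0.63 in 4878 regions outside input peaks, although per kb the former stood at 0.13.

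**Figure D2:**
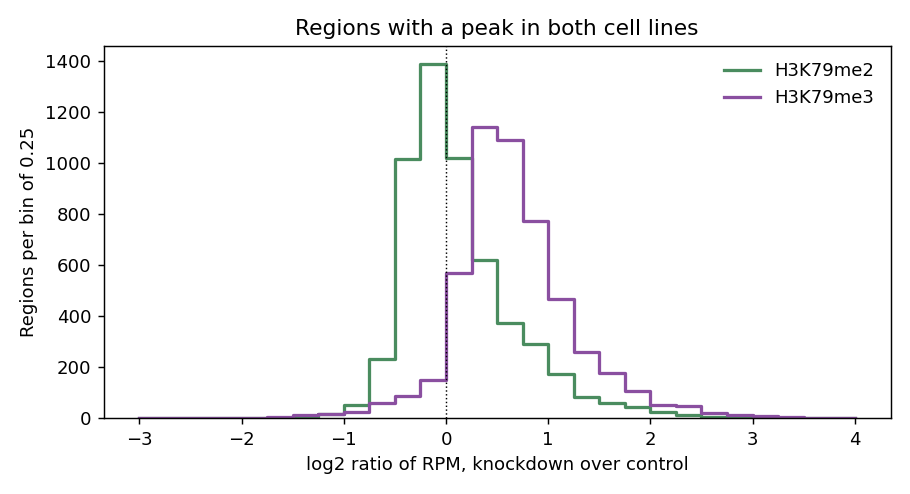
Histogram of the log2 ratio of RPM, knockdown over control, in regions with a peak in both cell lines (x axis; y axis, regions per bin of 0.25, values beyond the axis counted in the end bins), for H3K79me2 in green and H3K79me3 in purple. The dotted line marks equal tags: the H3K79me2 median is 0.00 (-0.15 per kb) and the H3K79me3 median 0.60 (0.55 per kb).

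The single-peak shared regions outside input peaks with the largest differences in tags per kb, chosen after their values were seen, are given by their log2 ratio per kb, knockdown over control, since called lengths differed. H3K79me3 at chromosome 12, 121900336 to 121904822 (hg19), had a ratio of 1.76 (counting SE 0.20), from 57 tags in 1891 bp in control and 439 tags in 4487 bp in knockdown cells. This region may lie in or near the KDM2B gene itself, the target of the hairpin, which was not settled because an annotation of hg19 was not used here, so its value may not stand for other sites. At chromosome 5, 179231143 to 179233898, the ratio was 1.69, and at chromosome 15, 75866822 to 75871530, it was 1.58. The lowest H3K79me3 ratio, -0.80, was at chromosome 7, 22550088 to 22551218, from 45 tags in 844 bp in control and 13 tags in 443 bp in knockdown cells. The log2 ratio of its summed tags was -1.73 (counting SE 0.45). The highest H3K79me2 ratio, 1.24, was at chromosome 9, 139937593 to 139940944, from 37 tags in 1269 bp and 189 tags in 3352 bp. The lowest, -1.45, was at chromosome 19, 4117440 to 4124559, from 441 tags in 1913 bp in control and 493 tags in 7120 bp in knockdown cells. Its summed tags ran the other way, 27.5 RPM in control and 37.5 in knockdown cells, a log2 ratio of 0.45.

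The marks shared most of their sites in each line. In control cells 66.7% of H3K79me2 peaks overlapped an H3K79me3 peak and 81.6% of H3K79me3 peaks overlapped an H3K79me2 peak. In knockdown cells the shares were 83.1% and 74.95%. Random placement gave mean overlaps of 1.41 to 1.801%, with a highest single value of 2.28%. The placements ignored where transcribed genes lie. They therefore do not separate sharing of sites by these marks from a common position over such genes. Merging the 4 lists gave 8899 regions, of which 3922 (44.1%) had a peak of both marks in both lines. The next most frequent combination, with 958 regions, had H3K79me2 in both lines and H3K79me3 in knockdown cells only. Its mirror image, H3K79me2 in both lines and H3K79me3 in control cells only, had 50 regions; this contrast was picked out after all 15 combinations had been counted. Regions with H3K79me3 in both lines and H3K79me2 in control cells only numbered 505, and those with H3K79me2 in knockdown cells only 98. The regions with H3K79me2 in 1 line were long, with medians of 5921 and 5998.5 bp, against 2285 bp for the 958 regions. In long regions a missing peak may be a missing call, as described below for the longest peaks.

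**Figure D3:**
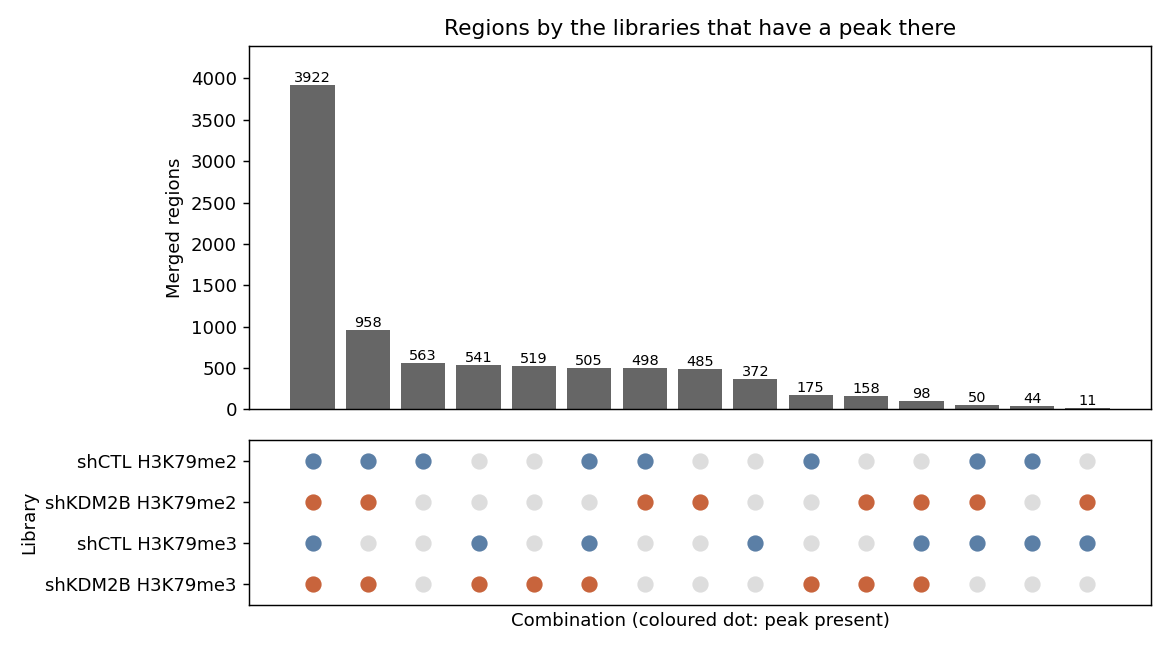
Number of merged regions (y axis of the upper panel) for each combination of libraries with a peak there; in the lower panel a coloured dot marks a library with a peak, blue for control and orange for knockdown. After the 3922 regions with all 4 peaks, the tallest bar is the 958 regions with H3K79me2 in both lines and H3K79me3 in knockdown cells only.

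H3K79me3 peaks found in knockdown cells only lay on control H3K79me2 peaks less often than the other knockdown H3K79me3 peaks did. Of the 1921 peaks, 1204 (62.7%, 95% interval 60.5 to 64.8%) overlapped an H3K79me2 peak of control cells, against 87.3% of the 5145 knockdown peaks with a control counterpart. The sets were not matched on width or tags, and the 1921 peaks were shorter, with a median width of 1148 against 2821 bp. The same count for H3K79me3 peaks in control only, set against knockdown H3K79me2 peaks, was 66 of 487 (13.6%, 95% interval 10.6 to 16.9%). Of those 487 peaks 81 lay on input peaks, and of the 1921 peaks 55 did. The excess of 958 over 50 regions was 19.2-fold, and it was 4.51-fold (510 against 113) with the same number of peaks from each list. The highest-scoring of the 958 regions lay at chromosome 19, 2475919 to 2477886, where knockdown H3K79me3 reached 9.21 RPM (95% interval 7.80 to 10.8) at a fold enrichment of 8.56. The next were at chromosome 5, 172195714 to 172198308, with 9.88 RPM, chromosome 8, 145063835 to 145065809, with 7.20, and chromosome 19, 12902300 to 12904432, with 7.69. Another lay at chromosome 17, 77751860 to 77753945, with 5.98.

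In the full lists, joint differences of the marks did not exceed the mean of draws matched on region length. These draws cannot decide whether the marks differed together, for the reason given at the end of this paragraph. Peaks of both marks in knockdown cells only were found in 158 regions, against 153 for independent lists and a mean of 189 in those draws. With the same number of peaks from each list, they were found in 114 regions, against 91.3 for independent lists and a mean of 101 in matched draws (the central 95% of draws reached up to 117). Peaks of both marks in control cells only were found in 44 regions, against 69.0 for independent lists and a mean of 90.5 in matched draws. Regions with H3K79me2 in control only and H3K79me3 in knockdown only numbered 175, against 262 for independent lists, and those with the opposite arrangement 11, against 40.3. Both comparisons rest on the same cell lines, and a region entered only if it had at least 1 peak. That entry rule by itself lowers coincidence below independence. For example, 485 regions entered only by a knockdown H3K79me2 peak and 519 only by a knockdown H3K79me3 peak. A count below the draws is therefore no evidence that the marks differed apart from each other.

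The difference in peak number was spread over the genome. On each of the 23 chromosomes examined (1 to 22 and X) the H3K79me3 list was longer in knockdown cells, with ratios from 1.14 on chromosome 7 to 1.38 on chromosome X. On each of them the H3K79me2 list was shorter, with ratios from 0.827 on chromosome 21 to 0.966 on chromosome 22. Chromosome 19 had the highest density of control H3K79me2 peaks, at 8.66 per Mb up to its last listed peak, and chromosome 13 the lowest, at 0.973 per Mb. For control H3K79me3 the same chromosomes stood at 6.67 and 0.938 per Mb. Chromosomes of the same libraries are not replicates.

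Input libraries gave few and narrow peaks. The control input had 927 peaks and the knockdown input 860, with median widths of 216 and 227 bp, which held 0.600% and 0.695% of the tags. Of the control input peaks 41.6% (95% interval 38.4 to 44.9%) were found in the knockdown input. Peaks on an input peak of either line made up 3.37% of control and 3.25% of knockdown H3K79me2 peaks, and 5.16% of control and 3.82% of knockdown H3K79me3 peaks. Without these peaks H3K79me3 gave 1868 peaks in knockdown only and 408 in control only.

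The longest peaks found in 1 line only were dense in tags but had scores of 50.3 to 82.1, near the calling threshold of 50. For H3K79me3 in knockdown only, the longest lay at chromosome 1, 93297361 to 93306378, with 203 RPM (95% interval 197 to 210) and a score of 64.0. The others lay at chromosome 5, 179125812 to 179134683 (180 RPM), chromosome 20, 32882318 to 32891166 (99.5), chromosome 3, 154033699 to 154042529 (118), and chromosome 22, 16184399 to 16193168 (156). For H3K79me3 in control only, they lay at chromosome 8, 144902474 to 144911565 (232 RPM), chromosome 5, 34912086 to 34920959 (106), chromosome 15, 101827091 to 101835915 (145), chromosome 19, 16646838 to 16655584 (106), and chromosome 2, 198380461 to 198389088 (82.0). No H3K79me2 peak was listed at any of these 10 positions in either line. An H3K79me3 peak of the other line lay within 10 kb of the control peaks on chromosomes 8, 5 and 15 and of the knockdown peak on chromosome 22.

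The longest H3K79me2 peaks in knockdown only lay at chromosome 12, 49447492 to 49456298 (108 RPM), chromosome 7, 26240942 to 26249451 (97.4), chromosome 1, 155896151 to 155904595 (77.7), chromosome 1, 54295894 to 54304288 (77.9), and chromosome 4, 177241024 to 177249407 (84.3). Those in control only lay at chromosome 1, 156714403 to 156723568 (206 RPM), chromosome 1, 226250170 to 226259172 (160), chromosome 22, 38893534 to 38902446 (161), chromosome 10, 1032820 to 1041690 (138), and chromosome 2, 113299721 to 113308520 (98.9). All 10 carried an H3K79me3 peak in both lines, except the chromosome 7 position, which carried it in knockdown cells only. The control H3K79me2 peak at 156714403 on chromosome 1 had a knockdown H3K79me2 peak within 10 kb. The ChIP lists held no peak wider than 9166 bp. In control H3K79me2, the median of RPM per kb was 5.47 in peaks of 3 to 5 kb and 7.91 in peaks over 7 kb, whereas the median score was 319 at 3 to 5 kb and 107 over 7 kb. The share without a counterpart was 11.3% at 3 to 5 kb (95% interval 9.75 to 12.9%) and 42.9% over 7 kb (95% interval 37.9 to 48.0%). In the other ChIP lists the share over 7 kb was lower. It was 11.1% for knockdown H3K79me2, 25.1% for control H3K79me3 and 20.9% for knockdown H3K79me3, against 4.22%, 5.75% and 10.7% at 3 to 5 kb.

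**Figure D4:**
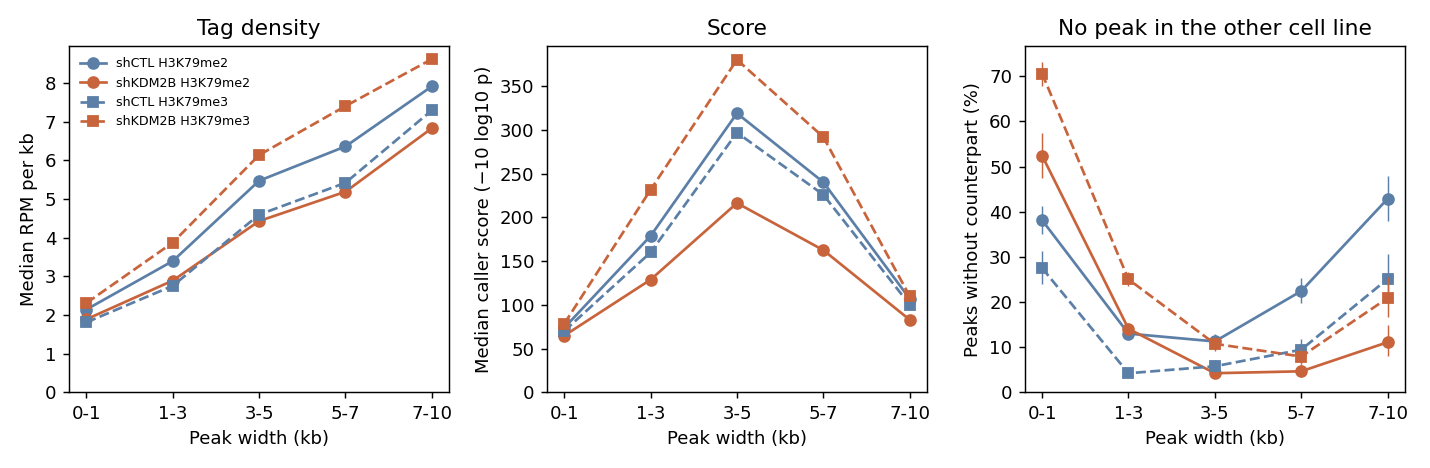
Median RPM per kb (left), median caller score (middle) and percent of peaks without a counterpart in the other cell line (right, with exact binomial 95% intervals) by peak width in kb, for the 4 ChIP libraries. Tag density is highest in the widest peaks of each library, while the score is highest at 3 to 5 kb and the share without a counterpart is higher again over 7 kb.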

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

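The tests of library depth for H3K79me3, of the general overlap by peaks with a counterpart, of the local background, and of the other mark at long peaks, taken mark by mark, were chosen after the result they bear on had been seen; the remaining tests in this part were fixed before their results.

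The marks differed in opposite directions between the lines, which was not tested because each group has 1 library. H3K79me3 peak number differed by 26.2% and H3K79me2 peak number by -9.29%. The share of tags in peaks differed by 4.55 percentage points for H3K79me3 and by -2.28 percentage points for H3K79me2. ChIP peaks were also found on the alternative chromosome 6 haplotype sequences, which the comparisons left out: 129 in control H3K79me2, 104 in knockdown H3K79me2, 88 in control H3K79me3 and 119 in knockdown H3K79me3, against 0 in either input.

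The excess of H3K79me3 in knockdown cells is not what depth would give, since the knockdown library held 0.962 of the control's filtered tags. Splitting by the shorter estimated fragment would not give it either, since the ratio of peaks joined within 1 kb was 1.23. Joining tests splitting only. The scanned window also follows the fragment estimate, 180 bp in control and 126 bp in knockdown cells, and its effect on short peaks was not tested. H3K79me3 peaks of up to 1 kb numbered 567 in control and 1154 in knockdown cells, and 815 of the latter lacked a control peak. Between the lines the fragment estimates differed in opposite directions for the marks, as did peak numbers. That H3K79me3 was higher and H3K79me2 lower is not what a swap of the knockdown marks would give, since the Jaccard index of covered length with control cells was higher with the library's own mark by 0.20 for H3K79me2 and 0.075 for H3K79me3. By number of overlapping peaks only knockdown H3K79me2 favoured its own mark, with 87.8% on control H3K79me2 and 66.0% on control H3K79me3. Knockdown H3K79me3 peaks lay on control H3K79me2 in 80.6% and on control H3K79me3 in 72.8%. A swap would need both libraries to favour the other mark. General overlap of the lists stays open for the position of knockdown-only H3K79me3 peaks on control H3K79me2. As it needs, 87.3% of knockdown peaks with a control counterpart lay there against 62.7%, in sets not matched on width or tags. The mirror share, the measure set beforehand, was 13.6% and went against it, though on other peaks than those in question. A higher yield of the whole H3K79me3 immunoprecipitation was taken to lift all sites alike, a premise that was not tested. Regions with H3K79me2 in both lines and in neither differed by 0.051 in median log2 ratio, within the bound set beforehand. Their median H3K79me3 length in control cells was 2323 and 5204 bp in that order. In long regions a missing H3K79me2 peak may be a missing call, so this contrast may not separate sites with and without H3K79me2. Regions with H3K79me2 in control only lay 0.24 above those with it in knockdown only, a comparison added afterwards. The 95% interval from resampled regions, which are not replicates, was 0.15 to 0.40 (0.24, interval 0.08 to 0.33, outside input peaks). That gap was smaller than the one set beforehand as counting against a yield, though its interval reached past that bound. Per kb the medians were 0.59 and 0.40, and the sets differed in length and tags. These values therefore do not decide. Of knockdown peaks above the control's median score 5.12% lacked a control peak, between the bounds set for weak sites crossing the threshold. An effect of KDM2B knockdown on H3K79me3 may be present and cannot be told apart from such a yield with 1 library per group and no external reference chromatin. For peak number, the shorter estimated fragment is not excluded as a contributor.

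The shorter H3K79me2 list of knockdown cells may follow in part from depth, which was not settled. With scores, though not reads, scaled to equal depth, the control list held 1.01 times as many peaks as the knockdown list, close to the equal number that depth alone would give. That scaling drops peaks by score, and peaks over 7 kb had low scores despite many tags. H3K79me2 peaks in control only and knockdown only numbered 199 and 44 at 5 to 7 kb, and 165 and 39 over 7 kb. The scaling therefore cannot separate depth from the local background of long peaks. The longer estimated fragment of the knockdown library is not excluded as a contributor, with a ratio of joined peaks, control over knockdown, of 1.08. An effect of the knockdown on H3K79me2 stays open and untested.

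The long peaks without a counterpart are a candidate artifact of calling without a control file. The caller took the local background from the same 10 kb of the library, so that a domain near that length would raise its own background: the highest median score of peaks over 7 kb among the ChIP lists was 110, below that of peaks of 3 to 5 kb in each of them, although tags per kb were higher. Of a real absence in the other line, it was laid down beforehand, for both marks together, that over 50% carrying the other mark there would argue against it; the pooled share was 58.9% (205 of 348, 95% interval 53.5 to 64.1%), which met that bound, but it pools 2 marks that lay on opposite sides of it, and the test was divided by mark only after the marks were seen to differ. By mark the share was 95.6% for H3K79me2, but it was 58.6% for unmatched H3K79me2 peaks of 3 to 5 kb, above the same bound, and the other mark does not show that this mark was present; for H3K79me3 it was 6.94%, which by that wording goes with a real absence, against 29.8% at 3 to 5 kb. The comparison with 3 to 5 kb was added afterwards, and for both marks a real absence cannot be told apart from a missing call, because the share itself followed width.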

How the results depend on the processing

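Of 148 values under another setting, 114 stayed within the bounds set for them. The bounds were a factor of 1.5 for a count or ratio, the 95% interval for a share of peaks, and the median counting SE for a log2 tag ratio. That factor is wide for ratios of peak number, covered length and tag share between the lines, all of which stayed within it. The H3K79me2 ratio of covered length, for example, was 1.00 in the main setting and 0.835 at the higher fold minimum. Chosen after the data were seen were the scaling to equal depth, summits within 1 kb, peaks within 10 kb, all sequences, the removal of peaks over 7 kb, all other settings of the tag ratio, the settings of the share of tags in peaks, and all settings for the regions with H3K79me2 in both lines. No paired analysis was possible because each group has 1 library. The alternatives by gene, gene list and distance to transcription start sites were not run, as no peak was assigned to a gene.

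With the same number of peaks from each list, the ratio of peaks in knockdown only to control only crossed 1, at 1.03 for H3K79me2 (811 in control only) and 0.998 for H3K79me3 (860 and 862); equal lists force it close to 1. With scores scaled to equal depth, the H3K79me2 ratio was 0.996, which lists of 6245 and 6193 peaks also force. Under the other settings run the ratio kept its side of 1 for both marks. With the higher-scoring 50% of each list, peaks in knockdown only and control only numbered 362 and 676 for H3K79me2 and 965 and 235 for H3K79me3, and 81 regions had new peaks of both marks, as shorter lists give. A reciprocal overlap of 50% gave 1299 H3K79me2 peaks in knockdown only and 860 H3K79me3 peaks in control only, and summits within 1 kb gave 751 of the latter. Regions with H3K79me2 in both lines and H3K79me3 in knockdown or control only numbered 486 and 20 in the higher-scoring 50%, 393 and 27 at the higher fold minimum, and 510 and 113 with equal numbers. Per kb, the H3K79me2 median log2 tag ratio was -0.15, as knockdown peaks were wider.

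The share of H3K79me2 peaks on H3K79me3 peaks was 76.6% (control) and 79.1% (knockdown) with equal numbers and 56.8% and 63.8% at 50% reciprocal overlap; the share of H3K79me3 on H3K79me2 peaks was 77.0% and 79.8%, and 69.2% and 55.9%. That last share was 73.0% in knockdown cells for the higher-scoring 50% and 82.7% in control cells without input peaks. Control input peaks found in the knockdown input were 34.8% at 50% reciprocal overlap, 46.6% within 1 kb and 68.6% for the higher-scoring 50%. Depth limits the weak peaks, and a missing peak gives no upper limit.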

Other observations

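The division of regions by combination of marks and by input was made after the data were seen; the test of conversion was fixed before its result, on regions picked out after they had been counted, and its values per kb were added later. The combination of marks sorted regions by size. Regions with a peak in all 4 ChIP libraries had a median length of 4011.5 bp, those with H3K79me3 in both lines and no H3K79me2 peak 6083 bp (541 regions), and those with H3K79me2 in both lines and no H3K79me3 peak 1531.5 bp (498 regions). A long domain may go uncalled against its own local background, so a missing H3K79me2 peak in long regions may be a missing call. Among H3K79me3 regions shared by both lines, the median log2 tag ratio, knockdown over control, was 0.61 where H3K79me2 was listed in both lines (3937 regions), 0.68 where it was listed in control only (508), 0.44 where it was listed in knockdown only (101) and 0.56 where it was listed in neither (541). In the 32 regions without H3K79me2 that lay on input peaks it was -0.53, although per kb the median log2 ratio there was 0.19.

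A hypothesis was that H3K79me3 appeared in knockdown cells at the expense of H3K79me2, by conversion of the one into the other. It predicted, before the result was seen, that H3K79me2 tags would be lower in the 958 regions with new H3K79me3 than in regions with all 4 peaks matched on control H3K79me2 tags. The median log2 H3K79me2 ratio was 0.52 in the 958 regions (interval of 0.46 to 0.59 from resampled regions of 1 library per line) and 0.21 in matched regions, a difference of 0.31 in the opposite direction. Most of the 0.52 went with wider knockdown peaks, by a median of 0.49 on the log2 scale: per kb the median was 0.02 in the 958 regions and -0.12 in matched ones. The set was also chosen on the outcome, because the 175 regions with new H3K79me3 and no H3K79me2 peak in knockdown cells were outside it by construction. The bound set beforehand therefore does not decide, and conversion stays open.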
